A study of Mus musculus with 2 samples.

How the data were processed

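RNA bound to the heterochromatin protein HP1 alpha was measured by enhanced crosslinking and immunoprecipitation (eCLIP) in NIH3T3, an established mouse fibroblast line. In this assay, ultraviolet light links proteins to the RNA they touch, the protein is precipitated with its RNA trimmed by RNase, and the RNA recovered from a gel region above the protein band is sequenced. Per the labels, 1 library was made with an antibody against HP1 alpha and 1 library was made without antibody and is called the input. Each group therefore has 1 library, and no difference between the groups has a replicate check.

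The authors deposited 1 table for both libraries. It holds read counts per gene, which are whole numbers that differ in total between the libraries, and a fold change. The submitters' processing notes name STAR 2.6.0c, featureCounts and the mouse build GRCm38, with no settings. Strand and whether reads were counted over exons or whole gene bodies are not given in the sources used here. Nor are the handling of reads that overlap several genes and the removal of PCR duplicates. The deposited ratio column is the count ratio times 1.66 in every row, and per the file headers this constant stands for total mapped reads. The columns are headed MEF rather than NIH3T3, and the control column is headed mock rather than input. The HP1 column was assigned to the antibody library and the mock column to the library without antibody, the only labelled sample that such a name fits. No other column of sample values was present (0).

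The table is a part of each library. It lists 3134 genes, and the larger of the 2 counts is at least 100 in every row. The listed counts add up to 513965 in the HP1 alpha library and to 830031 in the input. These totals are not sequencing depths. Because the input has more counts, only 16 genes have fewer than 100 counts there, against 1433 in the HP1 alpha library. Among genes at low level, those that are higher in the HP1 alpha library are therefore more often missed than those that are higher in the input. The 16 genes under 100 counts in the input were listed only through their HP1 alpha count, which fixes a ratio above 1 for them. Likewise, genes with the lowest HP1 alpha counts were listed only through their input count, which fixes a ratio below 1.

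Gene symbols were taken from the table. Positions, gene spans (first to last base, introns included) and RNA classes came from a RefSeq gene table of assembly GRCm38.p6, the build that the submitters' processing notes name. There 2969 genes matched by symbol, 120 matched by a synonym that belongs to 1 gene, and 45 did not match. RefSeq spans can differ from those of the annotation used for counting. In the protocadherin gamma cluster, 14 nested genes had counts that fell at each of the 13 steps from the first start to the last. This held in both libraries, so reads were shared between overlapping genes there. Counting over whole gene spans, introns included, would give such a fall in this cluster. Of the genes with a position, 141 overlapped another listed gene on either strand.

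Each count was divided by its library's total of listed counts. The ratio of HP1 alpha over input was formed per gene, with an exact 95% interval (Clopper-Pearson) from the binomial split of the 2 counts. Log2 ratios used a pseudocount of 0.5 counts. A gene was counted as higher or lower when its log2 ratio passed 2-fold and its interval excluded 1. All genes exceeded the minimum of 20 counts over both libraries, since the lowest sum was 121. The median interval had an upper bound 1.64 times its lower bound, and the widest had 2.84 times. Intervals cover counting error only, and reads may include PCR copies of one molecule. They compare these 2 libraries, not the conditions, and no p-value was computed. On simulated Poisson counts for the 3134 genes, 200 of them changed, the rule found 49 of 50 genes seeded 2.5-fold higher, 50 of 50 seeded 4-fold higher, 39 of 50 at 0.4 of the input and 50 of 50 at 0.25. It named 0 of 2934 unchanged genes.

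Before the data were examined, 11 gene lists were fixed, along with the rule for named genes. That rule takes Kcnq1ot1, the 12 highest and 6 lowest genes by the interval bound nearest to 1, the 5 most abundant genes of each library and up to 4 members of each list with the highest mean level. Some genes that this rule takes are not reported here or drawn with the lists, though they count in the list medians. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 10 rank bins, as a description of these libraries, and, after the data were seen, among lists matched on gene span in the same way. The lists of X-inactivation lncRNAs, structured small RNAs, snoRNAs and scaRNAs, mitochondrial transcripts and markers of other cell types (immune, epithelial and endothelial) had 0 members in the table and were not analysed here.

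Alternatives were TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 under R 4.3.3, a total without the 10 most abundant genes, other count minimums, a 4-fold threshold, a pseudocount of 5 and lncRNA genes alone. The authors' constant, a minimum of 400 counts, 1 gene per group of overlapping genes, ratios relative to the 200 genes nearest in span and the ribosomal list without kinases were added after seeing the data. Other steps used Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3.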

Results

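The table compared the RNA recovered with an HP1 alpha antibody with the input of NIH3T3 fibroblasts, to find long noncoding RNAs (lncRNAs) associated with HP1 alpha. Each group had 1 library, with 513965 listed counts for HP1 alpha and 830031 for the input. A gene's count had a median of 107 in the HP1 alpha library and 186 in the input. Every interval below is a 95% counting interval, every value rests on 1 library per group, and whether a difference exceeds the spread between replicates could not be tested.

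Kcnq1ot1, the imprinted antisense lncRNA that silences its neighbours in cis and for which the series is named, was higher in the HP1 alpha library. It had 145 counts there and 98 in the input, or 282 and 118 CPM of the listed total. The ratio was 2.39 (1.84 to 3.12), above 99.1% of the other listed genes. Among the 200 genes of most similar mean level its percentile was 100.0. Its 98 input counts lie under the listing limit of 100, so it was listed only through its HP1 alpha count. A ratio above 1 was therefore fixed by that limit, though not its full size, and both rankings carry this limit. Kcnq1ot1 (ENSMUSG00000101609.1) lies on chromosome 7 from 143213111 to 143296547 in GRCm38.p6, and no other listed gene with a known position overlapped it. The authors' deposited table gives a fold of 2.46, which uses total mapped reads.

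Over all listed genes, 74 were higher and 26 were lower in the HP1 alpha library than in the input. The remaining 3034 met neither rule. Airn, the imprinted antisense lncRNA that silences Igf2r in cis, had 824 counts against 424, a ratio of 3.14 (2.79 to 3.54). It lies on chromosome 17 from 12741311 to 12859884 and shares 28396 bases with Igf2r, whose ratio was 0.776 (0.677 to 0.888). The lncRNA 2610035D17Rik, on chromosome 11 from 113043906 to 113201838, had 332 against 171 counts and a ratio of 3.14 (2.6 to 3.79). Among protein-coding genes, Bckdhb, a subunit gene of the branched-chain ketoacid dehydrogenase, had the highest ratio in the table, 3.84 (2.83 to 5.27), from 145 and 61 counts. Its input count is the lowest of all listed genes, so it was listed only through its HP1 alpha count. Its call as higher therefore followed from the listing limit. The median log2 ratio of all genes was -0.21, and 968 of the 3134 genes had ratios above 1. With TMM factors, which shifted every log2 ratio by 0.20, the split became 127 higher and 9 lower, and with DESeq2 size factors, a shift of 0.21, it became 132 and 9. With the authors' constant it was 84 and 18. At a minimum of 400 counts, 46 higher genes and 1 lower gene were left.

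The other genes that the naming rule placed highest were mostly long protein-coding genes. Apex2, an endonuclease gene of base excision repair, had a ratio of 3.07 (2.55 to 3.71). Asb3, a member of the ankyrin repeat and SOCS box family, had 3.03 (2.39 to 3.85). The ratio was 2.73 (2.29 to 3.26) for Rassf8 and 2.49 (2.26 to 2.75) for Prkce, the gene of protein kinase C epsilon. Prkce was the most abundant of these genes, with 1055 counts in HP1 alpha and 683 in the input. Ube2e2, a ubiquitin-conjugating enzyme gene, had 2.52 (2.21 to 2.87). Glis1, a zinc finger transcription factor gene, had 2.80 (2.17 to 3.63). Cox16, an assembly factor gene of cytochrome c oxidase, had 2.84 (2.18 to 3.71) but lies within another listed gene, Gm20498, whose ratio was 2.24. Cox16 and Glis1 had 91 and 97 counts in the input, under the listing limit of 100, and were listed only through their HP1 alpha counts. The gene models ENSMUSG00000102836.1 and ENSMUSG00000103125.1, which had no match in the annotation, had identical counts of 757 and 489 and cannot be counted as separate genes. Of the 23 protocadherin alpha and gamma genes, 18 were among the 74, and 14 nested gamma genes had counts that fell stepwise along their cluster, so they are not independent either. With 1 gene kept per group of overlapping genes, 51 were higher and 23 were lower. These counts also leave out the genes without a known position, of which 7 were higher and 2 were lower.

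The 6 genes that the naming rule placed lowest included 2 snoRNA hosts. The snoRNA host gene 2810008D09Rik, now named Snhg20, was lowest, with 22 counts against 125 and a ratio of 0.284 (0.172 to 0.45). Timm23, a component of the mitochondrial import channel, followed with 0.301 (0.174 to 0.494). The ratio was 0.376 (0.246 to 0.560) for the zinc transporter gene Slc39a1 and 0.399 (0.279 to 0.560) for Snhg4. The transcripts 9330185C12Rik and Gm28967, which had no match in the annotation, had 0.333 and 0.424. Each of these 6 genes had 57 or fewer counts in the HP1 alpha library.

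**Figure D1:**
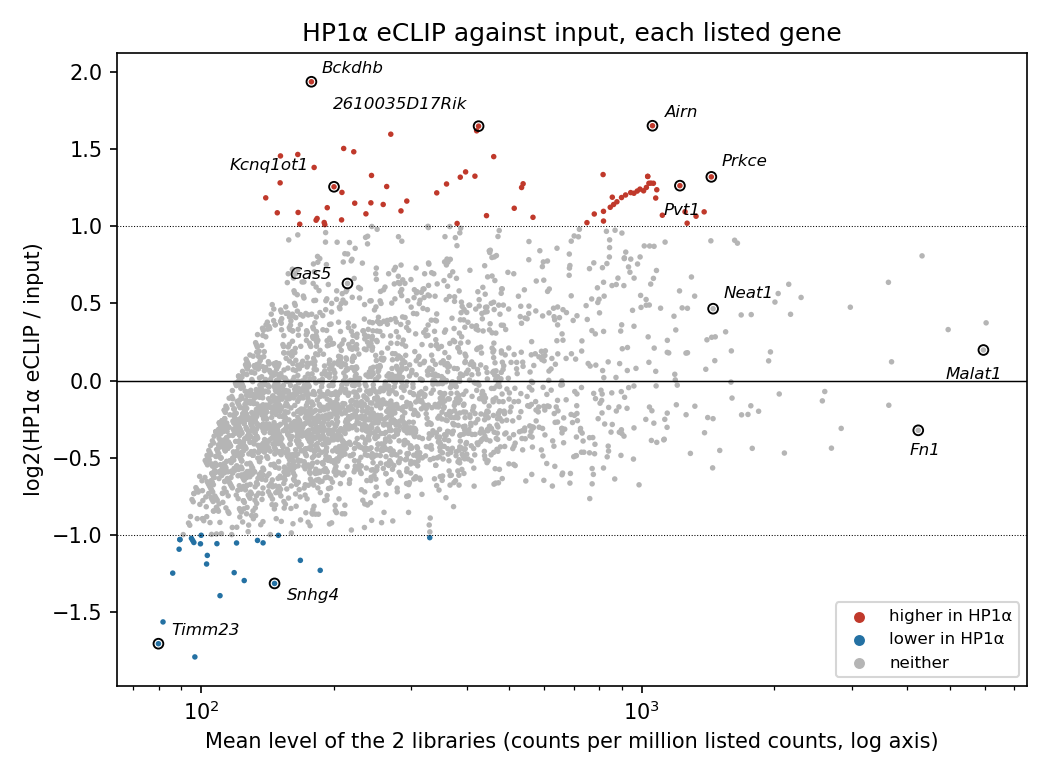
Each point is 1 listed gene, with its mean level in CPM of listed counts on a log axis and its log2 ratio of HP1 alpha over input on the vertical axis; dotted lines mark 2-fold. Kcnq1ot1 and Airn lie among the 74 genes coloured as higher, 26 are coloured as lower, and the slanted left edge follows from the listing limit of 100 counts.

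The most abundant RNAs differed by less than 2-fold. Rnf213, a ubiquitin ligase gene, led the HP1 alpha library with 3507 counts against 4371 in the input, a ratio of 1.30 (1.24 to 1.35). Malat1, the nuclear speckle lncRNA, led the input with 4608 counts against 3273 and had a ratio of 1.15 (1.10 to 1.20). Gm20388, which had no match in the annotation, had 1.26 (1.20 to 1.32). The transcription factor gene Mecom had 1.55 (1.47 to 1.65). Of the matrix genes, Fn1 had 0.800 (0.757 to 0.845). Col1a1 had 0.895 (0.844 to 0.949), a direction that turned under TMM and DESeq2 scaling.

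Every class of genes other than protein-coding took a larger share of listed counts in the HP1 alpha library, lncRNAs among them. The 30 lncRNA genes held 1.76% of its counts (1.72 to 1.80, exact binomial) and 1.39% (1.36 to 1.41) of the input, a ratio of 1.27 (1.23 to 1.30). The genes within the class diverged, and most of the gain in share came from the 4 that were higher. Of the 30, 4 were higher (Airn, 2610035D17Rik, Pvt1 and Kcnq1ot1), 2 were lower (Snhg4 and 2810008D09Rik) and 13 had ratios above 1. Their median log2 ratio was -0.074, at percentile 95.2 of level-matched and 99.73 of span-matched random lists. This median turned to 0.12 under TMM and 0.14 under DESeq2 scaling. Under either of these, 18 of the 30 had ratios above 1 and 6 were higher. The share ratio was 1.35 (1.32 to 1.38) for the 45 genes without a match in the annotation, whose class is unknown. It was 1.42 (1.29 to 1.55) for the 5 transcribed pseudogenes, with 891 and 1015 counts. Of these, 492 and 403 came from Pcdhgb8, 1 of the nested protocadherin gamma genes that share reads. Whether the gain is particular to lncRNAs could therefore not be decided. The 3054 protein-coding genes held 95.02% and 96.2% of the counts, with a median log2 ratio of -0.21.

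The fixed lists of noncoding RNAs went in different directions. Of the imprinted lncRNAs fixed beforehand, only Airn and Kcnq1ot1 were listed, and others such as H19 and Meg3 were not. Both were higher, with a median log2 ratio of 1.45, at percentile 100.0 of level-matched lists. That percentile describes these 2 genes and not imprinted lncRNAs as a class. Of these 2, Kcnq1ot1 was listed only through its HP1 alpha count, which fixed a ratio above 1. Of the 8 nuclear and chromatin lncRNAs, 1 was higher, Pvt1, the lncRNA next to Myc, with 885 against 596 counts and a ratio of 2.40 (2.16 to 2.67), which fell below 2-fold relative to genes of like span. The paraspeckle lncRNA Neat1 had 1.38 (1.26 to 1.51) and Tug1 had 0.984 (0.777 to 1.24). Dleu2 and 1810026B05Rik, also known as Chaserr, had intervals below 1, at 0.573 and 0.553. This list's median was 0.33, at percentile 99.2 of level-matched and 99.98 of span-matched lists. Of the 5 snoRNA hosts, 2 were lower and none was higher. Snhg3 had 0.595 (0.465 to 0.755), Snhg12 had 0.573 (0.444 to 0.734), and Gas5 went the other way with 1.55 (1.21 to 1.97). Their median was -0.80, at percentile 0.05 of level-matched and 0.82 of span-matched lists.

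The fixed lists of protein-coding genes held 1 gene that met the rule for higher or lower. Of the 11 mRNAs for heterochromatin proteins, 0 were higher and 0 were lower. Cbx5, which encodes HP1 alpha itself, had 429 and 780 counts and a ratio of 0.888 (0.788 to 1.00), and its direction turned under TMM and DESeq2 scaling. The remodeller gene Atrx had 0.806 (0.700 to 0.927), the corepressor gene Trim28 had 0.781 (0.643 to 0.945), and the methyltransferase gene Ehmt1 had 1.40 (1.19 to 1.65). The list's median log2 ratio was -0.35, at percentile 8.79 of level-matched and 24.42 of span-matched lists. Of the 11, 7 had intervals below 1, against 2 under TMM and 1 under DESeq2 scaling. The 8 fibroblast matrix mRNAs had intervals below 1, among them Col1a2 with 0.722 (0.667 to 0.782) and Col5a1 with 0.847 (0.770 to 0.931), and a median of -0.29, at percentile 2.51 of level-matched lists but 42.02 of span-matched lists. Under TMM and DESeq2 scaling, 4 of the 8 kept an interval below 1. Of the 16 genes found by a ribosomal protein prefix, 1 was lower, Rpl27a with 0.404 (0.274 to 0.582). Of the 16, 9 had intervals below 1, against 6 under TMM and DESeq2 scaling. Rps3 had 0.731 (0.605 to 0.880) and Rpl13a had 0.943 (0.769 to 1.15). The prefix also took in 3 kinase genes, among them Rps6kc1 with 1.55 (1.25 to 1.92). The median of the 16 was -0.50, at percentile 2.83 of level-matched and 12.53 of span-matched lists. That of the 13 ribosomal protein genes was -0.52, at percentile 18.16 of span-matched lists.

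**Figure D2:**
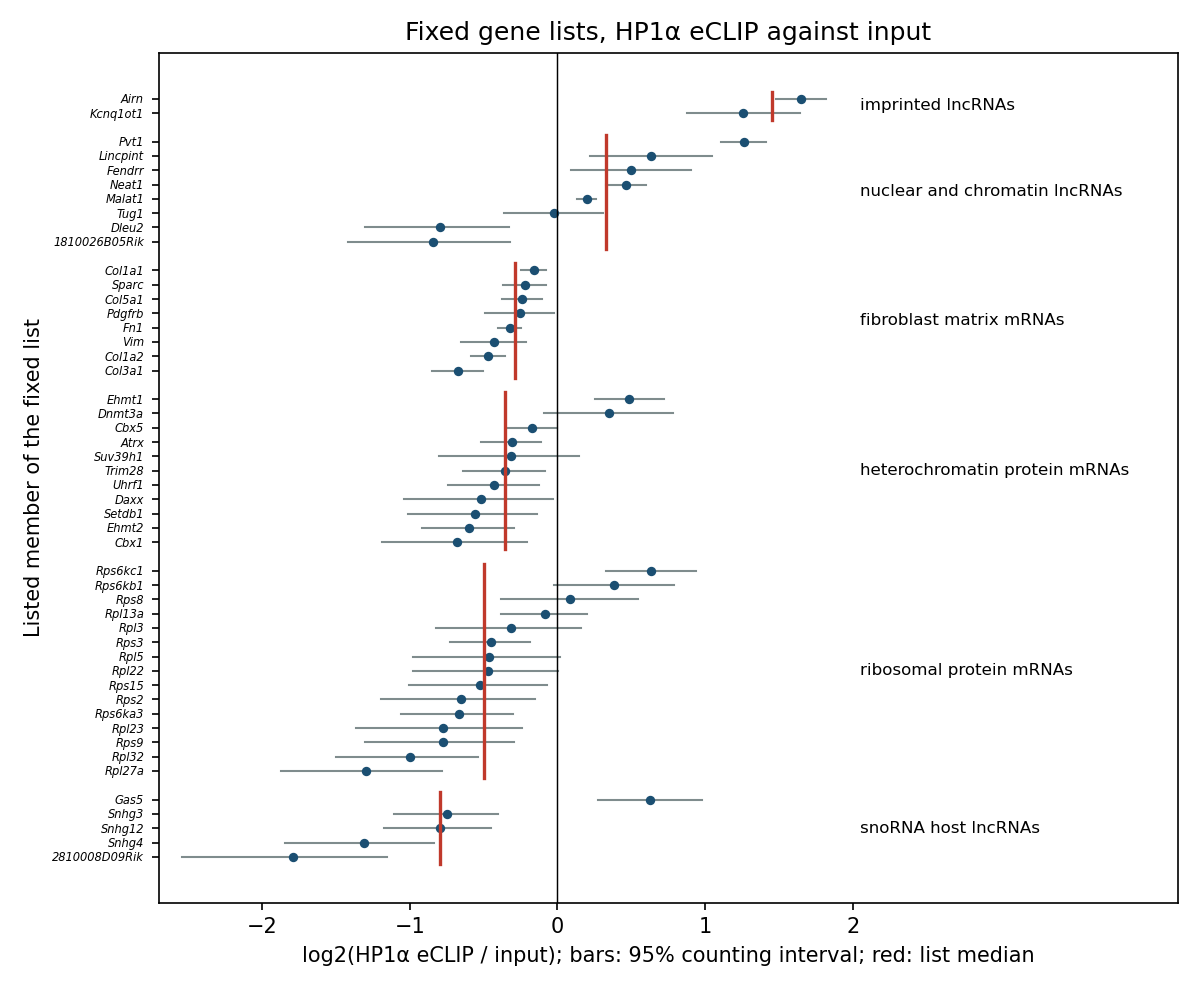
Log2 ratio of HP1 alpha over input for listed members of the fixed gene lists, each with its 95% counting interval as a bar and the list median as a red line. Airn and Kcnq1ot1 lie above 1 on this axis, while the snoRNA hosts other than Gas5 lie below 0.

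The ratio was larger in longer genes. Genes of up to 10 kb had a median ratio of 0.732, those between 50 and 100 kb had 0.892, those between 200 and 500 kb had 1.39, and the 52 genes above 500 kb had 1.55. Across the 3089 genes with a known span, Spearman's rho was 0.61 and Pearson's r with log10 span was 0.60. This is a correlation across genes, which are not independent replicates. The higher genes had a median span of 199 kb and the lower genes 11.3 kb, against 48.2 kb for all genes. Of the 67 higher genes with a known span, 57 spanned at least 100 kb, as did 781 of all 3089. Relative to the 200 genes nearest in span, 38 genes were higher and 4 were lower, and 28 of these 38 were among the 74. Of the 38, 12 were protocadherin gamma genes of 1 cluster. Relative to genes of like span, the log2 ratios of Prkce, Ube2e2 and Pvt1 were 0.79, 0.84 and 0.88, and those of Slc39a1 and Snhg4 were -0.94 and -0.86, all less than 2-fold. Kcnq1ot1 lay at percentile 99.5 of the 200 genes nearest to it in span and Airn at 100.0.

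**Figure D3:**
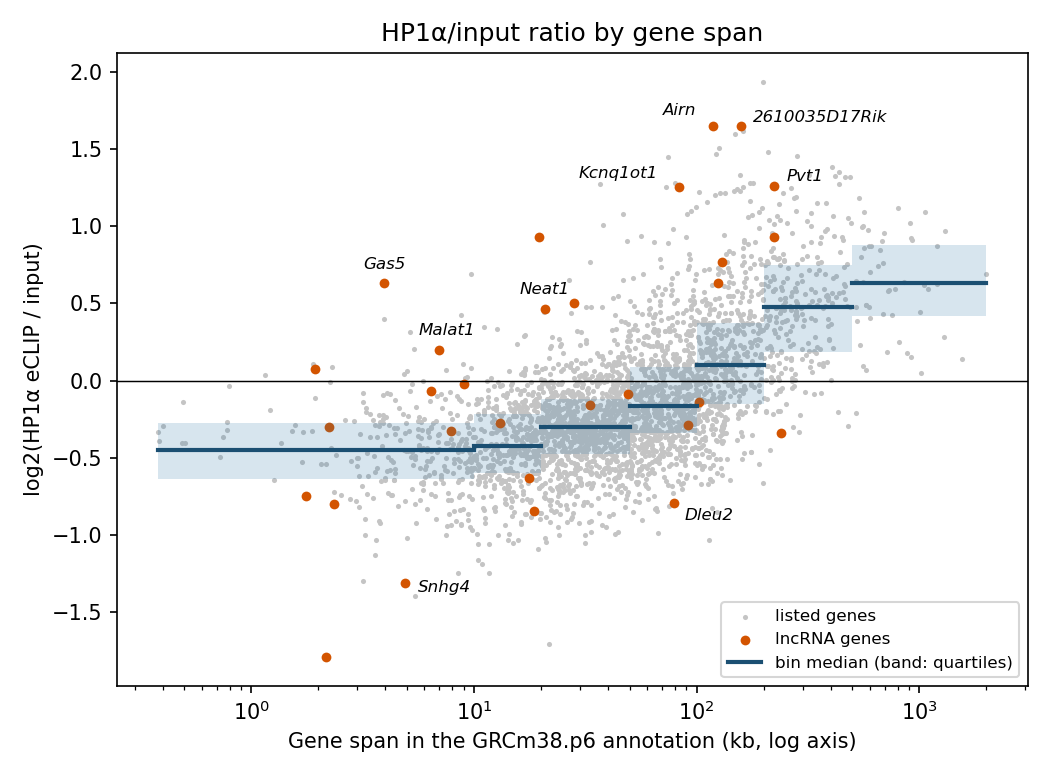
Log2 ratio of HP1 alpha over input against gene span in kb on a log axis, with lncRNA genes in orange and the median and quartiles of each span bin in blue. The bin medians go from -0.45 for genes up to 10 kb to 0.63 for those above 500 kb, and Airn and Kcnq1ot1 lie above genes of like span.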

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

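No paired analysis was possible because each group has 1 library. The planned minimums of 1 and 100 counts removed no gene. The number of higher genes, 74 as reported, was 127 with TMM and 132 with DESeq2 factors, each including all 74, because these scalings add a constant to every log2 ratio. It was 46 at a minimum of 400 counts, 4 among lncRNAs alone, 38 relative to genes of like span and 0 at 4-fold. The number of lower genes, 26 as reported, was 9 with TMM and 9 with DESeq2 factors, 1 at a minimum of 400 counts, 12 with a pseudocount of 5 counts, 2 among lncRNAs alone, 4 relative to genes of like span and 0 at 4-fold. Kcnq1ot1 stayed within its counting interval under the 4 other scalings, the larger pseudocount and the comparison with genes of like span. With TMM factors the list medians were 1.65 for imprinted lncRNAs, 0.53 for nuclear and chromatin lncRNAs, -0.60 for snoRNA hosts, -0.16 for heterochromatin mRNAs, -0.092 for matrix mRNAs and -0.30 for the ribosomal prefix. With DESeq2 factors they were 1.66, 0.54, -0.59, -0.15, -0.080 and -0.29 in the same order. Relative to genes of like span they were 0.62 for nuclear and chromatin lncRNAs, -0.35 for snoRNA hosts, -0.061 for heterochromatin mRNAs, -0.072 for matrix mRNAs and -0.045 for the ribosomal prefix. At a minimum of 400 counts they were 1.65 for imprinted lncRNAs (Airn alone), 0.47 for nuclear and chromatin lncRNAs and -0.27 for the ribosomal prefix, and with 1 gene per overlap group the nuclear and chromatin median was 0.47. The lncRNA class median of -0.074 changed sign to 0.12 with TMM factors, 0.14 with DESeq2 factors, 0.62 at a minimum of 400 counts and 0.29 relative to genes of like span, and was -0.033 with the authors' constant. The protein-coding median of -0.21 became -0.012 with TMM factors, 0.0001 with DESeq2 factors, 0.0031 relative to genes of like span, -0.20 without the 10 most abundant genes, -0.17 with the authors' constant, -0.082 at a minimum of 400 counts and -0.18 with a pseudocount of 5. Genes near 100 counts have wide intervals, so 2-fold differences there are the least certain.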

Other observations

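The tests of nuclear RNA and all comparisons with genes of like span were chosen after the ratios were seen. Each gene was compared with the 200 genes nearest to it in span. Of the lncRNAs outside the named set, Mir143hg (Carmn), a host of microRNAs of the smooth muscle lineage, had 241 against 204 counts and a ratio of 1.91, at percentile 100.0 of those genes, whereas 2610203C20Rik (Mir100hg) had 0.790, at percentile 1.5. Gas5, a member of a fixed list, had 2.12 times the median ratio of genes of like span, unlike the other snoRNA hosts. Among protein-coding genes, Vrk2, a serine/threonine kinase gene, had a ratio of 2.77, and the imprinted gene Sgce had 2.39. Vrk2, with 73 counts in the input, was listed only through its HP1 alpha count. At the other end, Pde4dip and Dennd5b had 0.630 and 0.485, both at percentile 0.0 of genes of like span. Dennd5b, with 30 counts in the HP1 alpha library, was listed only through its input count. The 11 replication histone genes, which lack introns, had a median ratio of 0.795, with 0 higher and 0 lower, at percentile 88.3 of lists matched on span. Apart from Gas5, these genes were chosen after their values were seen.

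The first pattern is the rise of the ratio with gene span (rho 0.61). With 1 gene per overlap group rho stayed at 0.61, but only 141 genes overlapped another listed gene, so it could hardly have changed. Among the 2948 genes with no listed overlapping gene, rho was also 0.61. This argues against reads shared between listed genes as the source, and reads shared with unlisted genes were not covered. The listing limit is argued against too, since rho was 0.68 among genes with at least 400 counts. A uniform background along the genome, such as DNA carried into the HP1 alpha library, is limited by Robo2, which had 140 counts over 1555.5 kb. A background of that density would supply 19.8% of the excess counts of the 298 genes of 200 kb or more. At the upper counting bound it would supply 23.4%. This limit holds only if reads were counted over introns, which the sources used here do not state. The stepwise fall in the protocadherin gamma cluster is what such counting would give, but it covers that cluster alone. A larger amount of nuclear, unspliced RNA in the HP1 alpha library is a candidate explanation. The median of the nuclear and chromatin lncRNAs lay at percentile 99.98 of lists matched on span, although Dleu2 and 1810026B05Rik went the other way. Of that list, Malat1 and Neat1 had ratios of 1.15 and 1.38, and Pvt1 had 2.40. Genes between 200 and 500 kb had a median ratio of 1.39 and those above 500 kb had 1.55. The list therefore does not show that nuclear RNA accounts for the rise in the longest genes. The median of all 30 lncRNAs lay at percentile 99.73, so a high position is not particular to that list. Uneven background, a difference in fragment length between the libraries and the missing replicates stay open, and exon and intron reads were not analysed here.

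The second pattern is the high ratio of Airn and Kcnq1ot1. The lower of their percentiles among genes of like span was 99.5. That rank decides little, since a ratio near the top of all listed genes ranks high in most sets of 200. The size of the gap says more. Genes of like span had a median log2 ratio of 0.024 for Airn and -0.15 for Kcnq1ot1. Their own log2 ratios were 1.65 and 1.25. These values argue against gene span alone for these 2 RNAs, although the listing limit fixed a ratio above 1 for Kcnq1ot1. Reads of a listed overlapping gene are argued against too: Igf2r, which shares 28396 bases with Airn, had a ratio of 0.776 (0.677 to 0.888), and Kcnq1ot1 had no listed overlapping gene of known position. With 1 library per group, variation between libraries may still account for part of both values and was not tested. A larger amount of nuclear RNA in the HP1 alpha library, the candidate for the first pattern, was not tested for these 2 RNAs. Of the 3089 genes with a known span, 3054 are protein-coding. Comparison with genes of like span therefore cannot separate that candidate from a preference of HP1 alpha for these RNAs. Such a preference stays a hypothesis, and reads from host genes that are not listed were not analysed here.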
